A study of Homo sapiens with 6 samples.

How the data were processed

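ATAC-seq, which marks open chromatin by inserting sequencing adapters with the Tn5 transposase, was performed on induced neurons made from HUES66, an established human embryonic stem cell line. Neurons were induced by doxycycline-driven NEUROG2 and NEUROG1 and collected at day 9. Per the labels, mouse glia were added to the cultures on day 5. Libraries came from 2 clonal lines with a heterozygous CHD8 deletion, CHD8-A and CHD8-B, and from their isogenic control, H66. Each line had 2 biological replicates that, per the labels' protocols, were cultured and tagmented separately, and libraries were read as paired ends of 37 bp.

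The deposited data are 6 peak lists, 1 per library, so these peaks were called library by library. Whether peaks were also called on pooled replicates is not given in the sources used here. Bowtie, Picard, MACS2 and bedtools and the build hg19 are named in the submitters' processing notes, with no versions, settings or order. Whether read ends were shifted for the Tn5 offset, and whether mouse reads from the glia were removed, is not given in the sources used here. Every peak end lay within its hg19 chromosome. The deposited score of each peak equals 10 times −log10 of its q-value, rounded down. The deposited fold enrichment is the ratio of the pileup at the summit to the local background of the same library, with 1 added to each. The deposited −log10 p and −log10 q values describe that summit, and the lowest −log10 q of a list lay between 1.31 and 1.37, next to the value for q = 0.05. Gaps in the authors' peak numbers showed that between 112 and 133 peaks had been removed from each list by a rule not given in the sources used here. Scores, folds and p-values are the authors' own values for each peak and were used to rank or filter peaks within a list.

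Read totals were not used here, so the depth was taken from the peak values. With fold enrichment written as (pileup + 1) / (background + 1) and p as the upper Poisson tail, a whole-number summit pileup and a background were recovered for 100% of peaks in each list, within 5e-05 of the deposited −log10 p. Backgrounds lay on steps of 0.02 tags, the step of 200 bp fragments over 10 kb, apart from 1 shared lowest value per library, taken as the genome-wide background. That value was between 0.517 and 0.525 tags in all 6 libraries. It reflects the tags used in peak calling, not the depth as sequenced, and the labels name no subsampling step. For an assumed effective genome of 2.7 Gb it equals about 6985495 to 7091767 tags per library. Pileups were therefore compared between libraries as values at nearly equal depth, a use chosen after the data were examined. Tested on simulated data, the recovery returned 99.995% of 20000 simulated peaks.

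Peaks of all libraries were merged into regions where they overlapped by at least 1 bp, and a region was called in a library that had a peak in it. Regions called in all 4 CHD8+/− libraries and in neither H66 library are named CHD8-only, and regions called in both H66 libraries and in none of the 4 CHD8+/− libraries H66-only. On simulated calls 100% of the regions made to belong to either class were found, which their set calls fixed in advance. The simulated H66 lists had a lower call rate at all other regions. There the CHD8-only class held 441 regions, many of them not made to belong to it, so shorter control lists alone add CHD8-only regions. The 4 CHD8+/− libraries were compared with the 2 H66 libraries by exact two-sided permutation of the library labels. There are 15 such splits, so the smallest possible p is 0.0667 and 0.05 cannot be reached. For each clone alone against H66 the smallest p is 0.333. P-values were adjusted over 23 chromosomes by the Benjamini-Hochberg method. Region counts were set against the other 14 splits. They were also set against 100 random reassignments of calls, a comparison not in the plan. These kept the number of libraries calling each region and the length of each list. Jaccard overlap in bp was computed with bedtools 2.31.1. The difference between pairs within a line and pairs between genotypes was tested over the 45 arrangements of the libraries into 3 pairs with a pair as control. The plan had named 15 splits into pairs for this test, and the 45 also count which pair is the control. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

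The comparisons, their tests, the alternatives and the rule for named items were fixed before the data were examined. Exceptions are those named as chosen later, as changed from the plan or as not in it. The rule names the 10 regions of each class with the highest value of the lowest within-list score percentile over the libraries calling them, and the 5 windows of 1 Mb with the largest rise and the 5 with the largest fall in mean share of peaks, among windows with at least 20 peaks per library on average. Alternatives were leaving out each library, autosomes only, the higher-scoring 50% of each list, lists shortened to the smallest list by score or by 20 random draws, an overlap of 50%, regions joined within 200 bp, a 1 kb distance from peaks of the other genotype, and splits restricted by replicate number. Comparisons planned on genes, namely the share of peaks at promoters, the enrichment of gene lists and the share of peaks near listed genes, were not run, because they need a gene annotation of build hg19, which was not used here. No region is assigned to a gene for the same reason. Chromosome Y was left out of the comparisons by chromosome, and random thinning there used 1 of the 20 draws. Some alternatives cannot move a value. Splits restricted by replicate number, the replicate block, reuse the main values. Keeping 50% of each list nearly fixes the log2 difference in peak number. Named regions stay in their class when a library is left out, or when chromosomes holding none of them are dropped.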

Results

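Open chromatin was mapped by ATAC-seq in day 9 induced neurons of 2 clonal CHD8+/− lines and their isogenic control. CHD8 encodes a chromatin-remodelling helicase of the CHD family and is associated with autism. CHD8-A, CHD8-B and H66 contributed 2 libraries each, 6 in all. The peak lists held 29209 and 29683 peaks for CHD8-A replicates 1 and 2, 29311 and 23932 for CHD8-B, and 17496 and 12637 for H66. The tag depth used for peak calling was nearly equal, with a genome-wide background of 0.519 ± 0.00188 tags (SD, n = 4) in CHD8+/− libraries and 0.525 ± 0.000881 tags (SD, n = 2) in H66 libraries. The labels name no step that brought libraries to a common depth, so the depth as sequenced is unknown. No list was a copy of another, since at most 10 peaks had identical ends in any pair of lists.

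The first comparison asked whether loss of a CHD8 copy went with a different amount of open chromatin. More peaks were called in both CHD8+/− clones than in the control. CHD8+/− lists held 28034 ± 2742 peaks (SD, n = 4) and H66 lists 15067 ± 3436 peaks (SD, n = 2), a difference of 0.91 in mean log2 peak number. The difference was 0.99 for CHD8-A and 0.83 for CHD8-B. All 4 CHD8+/− lists were longer than both H66 lists, and the exact permutation p was 0.0667, the smallest this design allows. Peaks covered 11.1 ± 1.61 Mb (SD, n = 4) in CHD8+/− and 5.78 ± 1.52 Mb (SD, n = 2) in H66 libraries, a log2 difference of 0.95 with the same exact p of 0.0667 (1.12 for CHD8-A and 0.79 for CHD8-B). Mean peak width was 394 ± 28.5 bp (SD, n = 4) against 382 ± 13.9 bp (SD, n = 2), with an exact permutation p of 0.533. Mean width was 419 ± 1.33 bp (SD) in CHD8-A and 370 ± 6.01 bp (SD) in CHD8-B, on either side of the H66 mean. CHD8-B overlapped H66, with 366 and 374 bp in its libraries against 392 and 372 bp in those of H66.

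Peaks at shared regions were also taller in CHD8-A. At the 9467 regions called in all 6 libraries, the geometric mean summit pileup was 31.7 and 31.2 tags in the CHD8-A libraries, 22.4 and 21 in CHD8-B, and 19.2 and 15.9 in H66. The CHD8+/− mean was 26.6 ± 5.65 tags (SD, n = 4) and the H66 mean 17.5 ± 2.31 tags (SD, n = 2), with an exact permutation p of 0.133. The share of peaks with a pileup of 30 tags or more was 20.1 ± 0.495% (SD) in CHD8-A, 7.95 ± 0.311% (SD) in CHD8-B and 5.88 ± 2.76% (SD) in H66, n = 2 each. Over all peaks of a list the median pileup was 14 ± 0 tags (SD) in CHD8-A, 13.5 ± 0.707 in CHD8-B and 14 ± 0 in H66, n = 2 each. CHD8-B replicate 1 had about as many peaks as CHD8-A but lower ones. With pileup and background scaled to the weakest library and a −log10 p of at least 4 required, the log2 difference in peak number was 0.64 by medians and 0.68 by geometric means, with no overlap between genotypes. With at least 8 required it was 0.14 and 0.22, and by medians both CHD8-B lists (12759 and 13041 peaks) stayed longer than both H66 lists (10646 and 9775), while those of CHD8-A (9574 and 10154) did not. These alternatives were chosen after the data were examined.

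**Figure D1:**
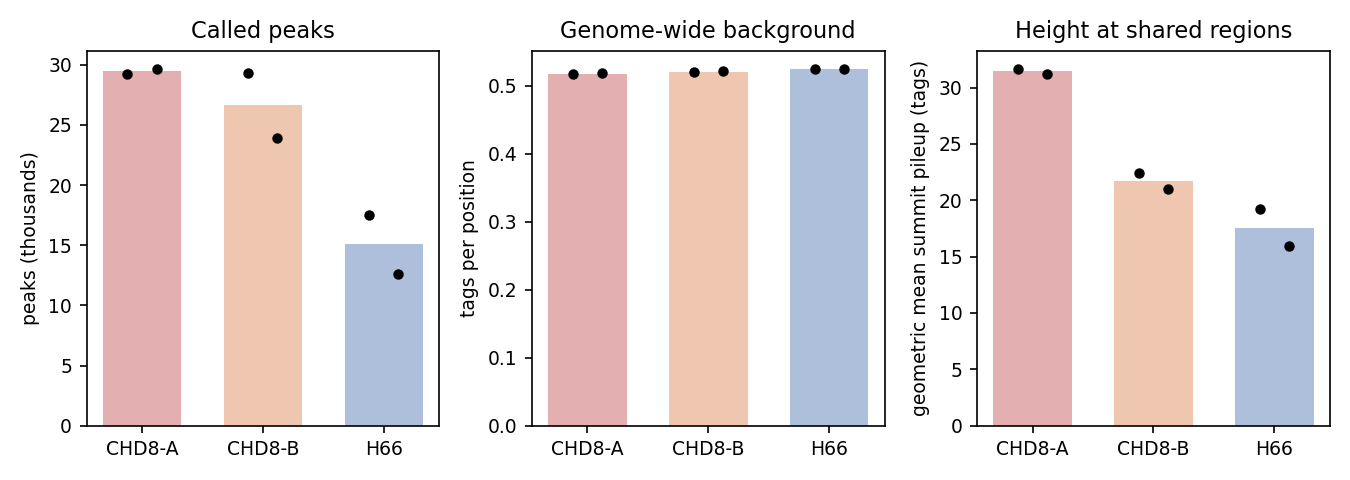
Called peaks (in units of 1000), genome-wide background (tags per position) and geometric mean summit pileup at shared regions (tags) for the 3 lines. Bars are means of 2 libraries and points are single libraries. Backgrounds lie between 0.517 and 0.525, while peak numbers range from 12637 to 29683.

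Next, single regions were compared. The 6 lists merged into 45364 regions, of which 16650 were called in a single library. CHD8+/− neurons retained most control regions, since 91.5% of the 10349 regions called in both H66 libraries were called in all 4 CHD8+/− libraries. CHD8-only regions numbered 2653, or 17.5% of the 15142 regions called in all 4 CHD8+/− libraries. H66-only regions numbered 112, or 1.08% of those called in both H66 libraries. Among the 15 splits of the libraries into 4 and 2, the largest count of regions called only in the 4 was the real one, and the next was 450. For regions called only in the pair, the highest count was 2000, for the CHD8-A pair, so the H66-only count was not large among splits. Random reassignment of calls at fixed list lengths, not in the plan, gave 2031 ± 25.8 CHD8-only regions (SD over 100 draws) and 8.73 ± 2.97 H66-only regions. Both observed counts lay above all draws (one-sided permutation p = 0.0099 each, the smallest 100 draws can give). Such draws also remove the likeness of replicates, so they test calls spread at random over libraries and not genotype alone.

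CHD8-only regions were small, as were H66-only regions, and lay slightly farther from shared regions than other regions did on average. In the 4 libraries calling CHD8-only regions, their median pileup was 12 or 13 tags and their median peak width 280 to 309 bp. In the same libraries, regions called in all 6 had 20 to 32 tags and 450 to 618 bp. H66-only regions had medians of 11 and 10 tags and 272.5 and 250 bp in H66 replicates 1 and 2, so small size was not particular to CHD8-only regions. The median distance of CHD8-only regions to the nearest region called in all 6 libraries was 113.8 kb. In 100 random draws of other regions it was 103.5 kb on average, with a range of 93.3 to 116.7 kb (two-sided permutation p = 0.0396). These draws take regions as units, so the p does not measure the spread between libraries. With equal list lengths these distances were 150.3 kb and 125.6 kb, with a permutation p of 0.0594. H66-only regions lay at a median of 85.2 kb against 108.2 kb in random draws (permutation p = 0.257).

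The CHD8-only region with the highest scores lay on chromosome 16 from 4466413 to 4466967 (hg19), with pileups of 40 and 44 tags in CHD8-A and 24 and 25 in CHD8-B. The other 9 named CHD8-only regions had lowest pileups between 17 and 23 tags over the 4 libraries. Among them, the region on chromosome 9 from 6015473 to 6015859 had a pileup of 18.8 ± 0.957 tags (SD, n = 4). Further regions on chromosome 9 lay from 87232568 to 87233040 with 22.3 ± 1.26 tags and from 124505696 to 124506081 with 23.3 ± 4.57 tags. On chromosome 4 the region from 83705944 to 83706396 had 24.8 ± 1.71 tags. On chromosome 5 the regions from 123987258 to 123987665 and from 1125044 to 1125443 had 25.3 ± 4.50 and 22 ± 4.24 tags. The remaining ones were on chromosome 2 from 202852107 to 202852601 (20.8 ± 2.22 tags), on chromosome 1 from 39624202 to 39624755 (25.5 ± 6.61 tags) and on chromosome 15 from 53813176 to 53813700 (20.3 ± 2.87 tags). In a library without a call the pileup of these regions is unknown.

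The highest-scoring H66-only region lay on chromosome 2 from 121223683 to 121224170, with 19 tags in both H66 libraries. The next were on chromosome 19 from 37742449 to 37742942 (14.5 ± 2.12 tags, SD, n = 2), on chromosome 1 from 156084247 to 156084825 (14.5 ± 0.707 tags) and on chromosome 11 from 20048656 to 20049121 (15 ± 1.41 tags). Chromosome 4 held a pair of them, from 184104514 to 184104790 with 14 ± 2.83 tags and from 62858120 to 62858400 with 11 ± 1.41 tags. The regions on chromosome 3 from 66848481 to 66848964 and on chromosome 19 from 6767307 to 6767955 each had 12.5 ± 0.707 tags. The last named regions, on chromosome 2 from 149571177 to 149571504 and on chromosome 12 from 5331282 to 5331647, had 11 and 10 tags in both libraries.

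The counts were next compared at equal list length. With each list shortened to its 12637 highest-scoring peaks, 20802 merged regions remained, 6774 were called in all 6 libraries, 279 were CHD8-only and 383 were H66-only. Equal length favours the H66-only class, which needs 2 calls where CHD8-only needs 4, and in 9 of the 12 splits whose pair mixed lines more regions were likewise called only in the pair. At this length the split with the highest counts was the one that set CHD8-B apart, with 640 regions called only in the CHD8-B pair and 373 called in all libraries but that pair. Splits whose pair mixed lines gave at most 142 and 130 such regions. Leaving out H66 replicate 1, H66 replicate 2 or CHD8-B replicate 2 from the full lists gave 5098, 3237 and 4027 CHD8-only regions and 360, 1199 and 120 H66-only regions.

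**Figure D2:**
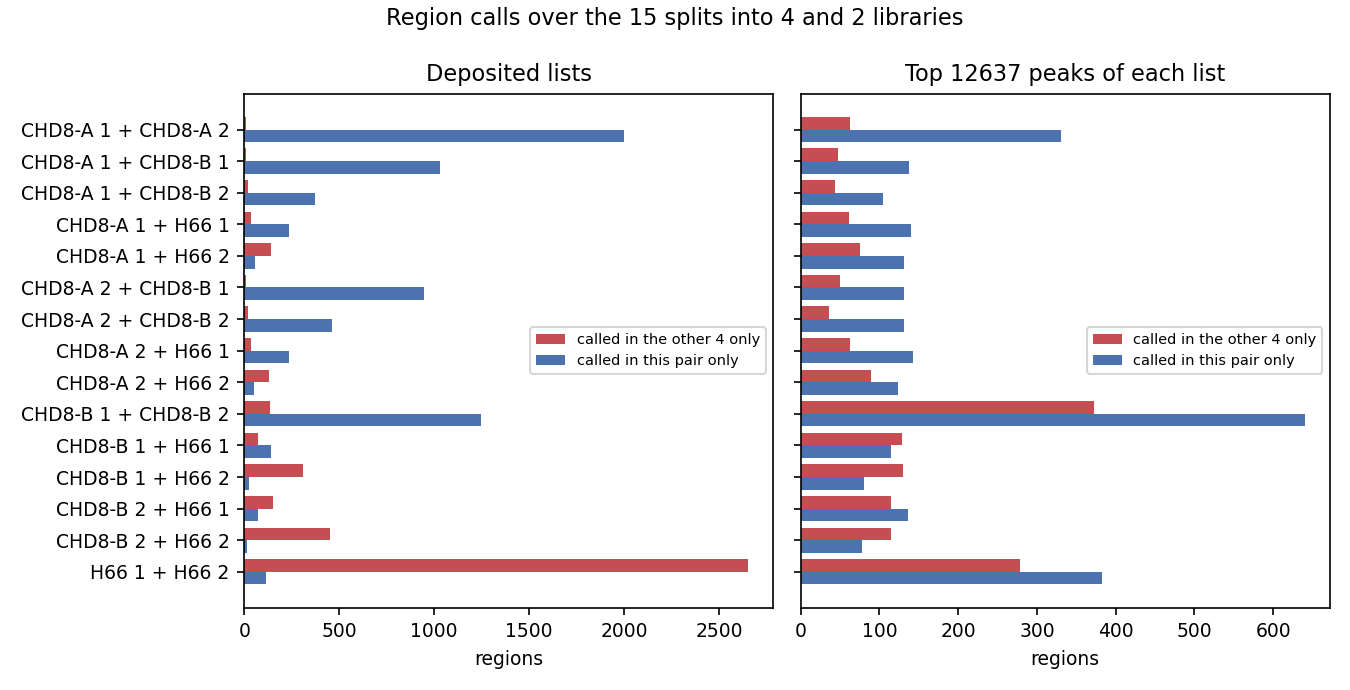
Number of merged regions (x axis) called only in a pair of libraries (blue) or only in the other 4 (red), for each of the 15 pairs (y axis; numbers after line names are replicates). In the full lists the H66 pair stands out with 2653 regions called only in the other 4, and at 12637 peaks per list the CHD8-B pair has the highest counts, 640 and 373.

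On average, lists of the same line were more alike than lists of different genotypes. Mean Jaccard overlap was 0.516 for pairs within a line and 0.390 for pairs between genotypes. The difference was 0.126 (exact permutation p = 0.0222, the smallest of 45 arrangements, a count changed from the plan). At equal list length the mean overlaps were 0.573 against 0.482. The H66 pair, at 0.479, lay above every pair between genotypes (at most 0.448) but below 3 of the 4 pairs of CHD8-A with CHD8-B. At equal list length H66 replicate 1 overlapped both CHD8-A lists by 0.525 and H66 replicate 2 by 0.514. Lists of CHD8-A and CHD8-B overlapped by 0.481 on average, above CHD8-A with H66 at 0.384 and CHD8-B with H66 at 0.396. At equal list length these means were 0.516, 0.497 and 0.467. With either H66 library left out the exact p was 0.0667, the smallest with a single control library, and with lists thinned at random the difference was 0.029 (exact permutation p = 0.156).

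Agreement of the clones was then examined. CHD8-A had 6705 regions called in both its libraries and in neither H66 library, and CHD8-B had 5296. They shared 2653 of these, which by definition are the CHD8-only regions, against 1292 for independent lists and 2031 in random reassignment. In the other direction, 145 regions of both H66 libraries were called in neither CHD8-A library and 325 in neither CHD8-B library. They shared 112, the H66-only regions, against 4.55 for independent lists and 8.73 in random reassignment. The shared counts and their reassignment values are thus those given above and no separate evidence. At equal list length, 870 regions of CHD8-A and 1235 of CHD8-B were called in neither H66 library. In the other direction 534 H66 regions were called in neither CHD8-A library and 956 in neither CHD8-B library. Both comparisons use the same H66 libraries, which cannot be split further, so part of the excess of shared regions may come from the shared controls. The clones also differed from each other, with 2646 regions called in both CHD8-A and neither CHD8-B library and 1371 the other way. These counts were 1069 and 900 at equal list length. Without CHD8-B replicate 2, where fewer calls are required of CHD8-B, they were 3867 and 6403, and with lists thinned at random 1563.5 and 1711, so the order of the clones turned in both.

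Peaks were more numerous in CHD8+/− libraries along the whole genome. Of 1937 windows of 1 Mb with at least 5 peaks on average, 1929 held more peaks in CHD8+/− than in H66 libraries on average, 1927 in CHD8-A and 1884 in CHD8-B, with a median ratio of 1.83. As shares of each list, however, peaks were distributed differently. Chromosome 19 held 4.61 ± 0.353% of CHD8+/− peaks (SD, n = 4) and 6.67 ± 0.513% of H66 peaks (SD, n = 2), lower in 4 of 4 libraries (exact permutation p = 0.0667, adjusted p = 0.256). Chromosome 8 held 4.598 ± 0.194% against 3.92 ± 0.0630%, chromosome 5 held 5.78 ± 0.250% against 5.13 ± 0.298%, and chromosome 13 held 2.58 ± 0.185% against 2.15 ± 0.172%, each higher in 4 of 4 libraries with the same exact p and adjusted p. Genotypes did not overlap on 10 of 23 chromosomes, 8 higher and 2 lower in CHD8+/−, where chance gives 3.07. Without H66 replicate 1 the number was 18 and without H66 replicate 2 it was 11, where chance gives 9.2 in each case. The excess was thus small once H66 replicate 2 was left out. No chromosome passed the adjusted test, which this design cannot reach. With lists shortened by score to equal length genotypes did not overlap on 2 chromosomes, and the chromosome 19 difference was −0.88 percentage points in place of −2.07. With lists thinned by 1 random draw, which on average keeps the shares, these were 11 and −2.11.

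**Figure D3:**
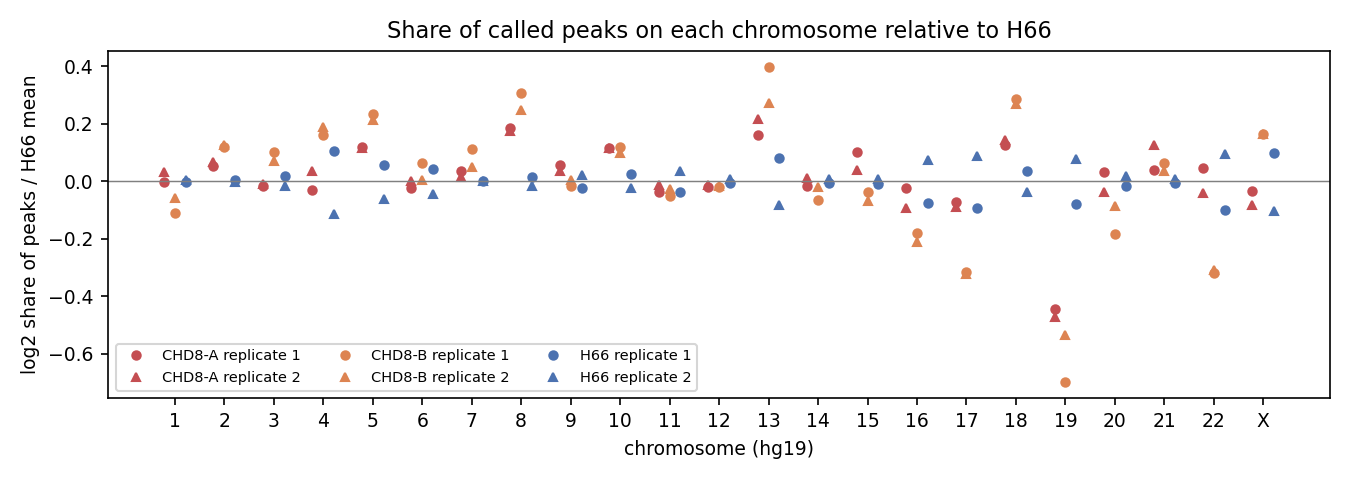
Share of called peaks on each chromosome (x axis) as the log2 ratio to the mean of the H66 libraries (y axis), with a point per library. On chromosome 19 all 4 CHD8+/− libraries lie below both H66 libraries, with mean shares of 4.61% and 6.67%.

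Among the 155 windows with at least 20 peaks on average, all held more peaks in CHD8+/− libraries on average, while 11 held a higher share. The largest falls in share were in windows of chromosome 19 from 1 to 2 Mb (0.142 ± 0.0181% against 0.249 ± 0.0615% of peaks), from 58 to 59 Mb (0.159 ± 0.0141% against 0.259 ± 0.0261%) and from 17 to 18 Mb (0.110 ± 0.0174% against 0.192 ± 0.00312%), and of chromosome 16 from 2 to 3 Mb (0.128 ± 0.0129% against 0.212 ± 0.0249%) and from 30 to 31 Mb (0.177 ± 0.0203% against 0.260 ± 0.0357%; SD, n = 4 and 2, exact permutation p = 0.0667 each). These windows were picked for their falls, and 84 of the 155 windows reached this same smallest p, so it is not particular to them. Adjusted over windows by the Benjamini-Hochberg method, the lowest exact permutation p was 0.123. The named windows were already dense in H66. The window of chromosome 19 from 1 to 2 Mb held 39.5 peaks on average in CHD8+/− and 36.5 in H66 libraries. The largest rises had exact permutation p of 0.2 or more. They were on chromosome 15 from 74 to 75 Mb (26 peaks against 9.5 on average, exact permutation p = 0.2), chromosome 1 from 204 to 205 Mb (p = 0.533), chromosome 6 from 28 to 29 Mb (p = 0.267), chromosome 9 from 132 to 133 Mb (p = 0.667) and chromosome 17 from 17 to 18 Mb (p = 0.467). Without H66 replicate 2 the share of the window on chromosome 1 was lower in CHD8+/− libraries, by −0.0178 percentage points.

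Chromosome 20 differed between the lines in a way that followed its arms, a comparison chosen after the data were examined. Summit pileups at regions called in all 6 libraries were centred on the autosomes other than chromosome 20. On the short arm, at 70 regions up to 26.2 Mb, mean centred log2 pileup was 0.26 ± 0.017 (SD, n = 2) in CHD8-A, −0.16 ± 0.060 in H66 and −0.49 ± 0.014 in CHD8-B. On the long arm, at 192 regions from 30.1 Mb, the order was opposite, with −0.14 ± 0.039 in CHD8-A, 0.10 ± 0.063 in H66 and 0.28 ± 0.048 in CHD8-B. CHD8-A minus CHD8-B was 0.76 on the short arm and −0.42 on the long arm, while it lay between −0.11 and 0.16 on the other autosomes. The short arm held 0.941 ± 0.0107% of peaks (SD, n = 2) in CHD8-A, 0.739 ± 0.0942% in H66 and 0.555 ± 0.00752% in CHD8-B. On the long arm the shares did not follow the pileup, with 1.70 ± 0.0818%, 1.90 ± 0.139% and 1.85 ± 0.108%. Pooled over both clones, the CHD8+/− minus H66 difference was 0.042 on the short arm (exact permutation p = 0.733) and −0.032 on the long arm (exact permutation p = 0.8).

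**Figure D4:**
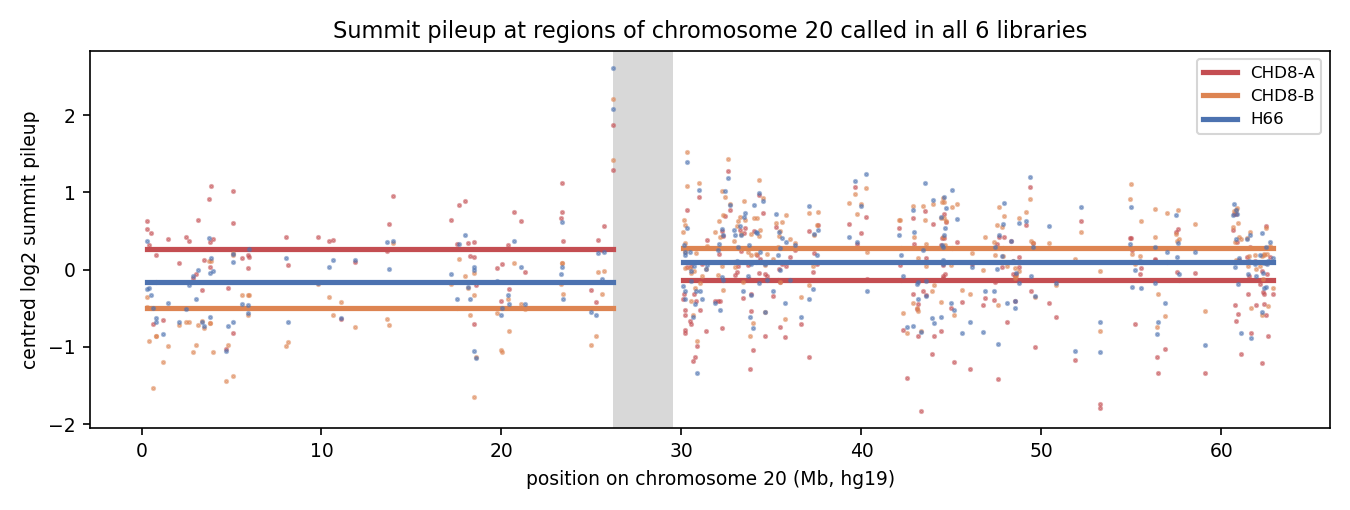
Centred log2 summit pileup (y axis) along chromosome 20 (x axis, Mb, hg19) at regions called in all 6 libraries. Points are means of the 2 libraries of a line, horizontal lines are arm means, and the grey band is the gap from 26.2 to 29.5 Mb without a merged region of any library. CHD8-A lies above CHD8-B on the short arm by 0.76 and below it on the long arm, by −0.42.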

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

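For the patterns below, the tests of sequencing depth, of a common p-value limit, of neighbouring blocks on chromosome 20 and of chromosome 19 pileup were chosen after the result was seen. The scaling was also repeated with geometric means, at stricter limits, over the strongest 25% of shared regions and for each clone after its first result was seen.

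Peak number in CHD8-B replicate 2, at 23932, stood far below the other 3 CHD8+/− libraries, with a gap of 0.918 of the whole range. Of 29 such checks on library measures and chromosome shares, 1 met the limit, where chance gives about 1.45. Of the technical explanations for the longer CHD8+/− lists, depth in peak calling is argued against, since the H66 background was 1.01 times that of CHD8+/− libraries (libraries may have been subsampled to a common depth, so this says nothing of the depth as sequenced), and so is a stricter p-value limit in the shorter lists, since a common −log10 p of at least 8 left a log2 difference of 0.83, and 89.3% or more of the full difference whichever library was left out. Uniformly lower enrichment in H66 is argued against as the whole cause for CHD8-B, since both its lists stayed longer than both H66 lists in all 24 scaled settings (limits of −log10 p from 4 to 10), by 0.24 to 0.78 in log2 and at least 2.90 pooled SD between replicates. For CHD8-A it stays open, since the scaled difference ranged from −0.049 to 0.59. Over both clones the first scaling, by medians at a limit of 4, left 0.64 without overlap and so met the bound set against this explanation, but that bound was wrong, since 35.5% and 37.8% of scaled CHD8-A, 32.0% and 20.1% of CHD8-B and 13.1% and 3.54% of H66 peaks lay between 4 and 6, a range that held at most 10.1% of peaks in any unscaled list. A genotype effect on chromatin opening and lower enrichment of the H66 libraries cannot be told apart for CHD8-A with a single control line. For CHD8-B the scaling tested uniform enrichment only. The difference left in that clone cannot be assigned to genotype either, since other differences between the lines or libraries were not tested.

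The next flags mark features where both CHD8-A libraries lay on one side of both H66 libraries and both CHD8-B libraries on the other. Only those on chromosome 20 were tested further. Among 47 features looked at, 6 did so, where chance gives about 1.04. Only chromosome 20 was split into arms, a split chosen after the data were examined, and both arms are among the 6. The chance number assumes features chosen in advance, so the excess is no test of the arms. On chromosome 20, CHD8-A minus CHD8-B in centred log2 pileup was 0.76 on the short arm and −0.42 on the long arm. Chance variation between neighbours is argued against, since 0% of 7468 blocks of 70 consecutive regions on other autosomes reached the short-arm difference, and so are a few strong regions, since 95.7% of short-arm regions were higher in CHD8-A. A candidate explanation is that the lines differ in copy number of the arms. As this needs, the median local background around peaks, relative to other autosomes, differed by 0.25 on the short arm and −0.47 on the long arm in log2, beyond the largest SD between replicates of 0.058, but the short-arm difference was smaller than that in pileup, and H66 (−0.32) lay next to CHD8-B (−0.37) there, although CHD8-B minus H66 in pileup was −0.34. Background and pileup come from the same tags, and wide open domains raise both, so a karyotype of the cultures used would be needed to settle it, and a regulatory difference between the lines was not tested.

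The other features of this kind were the pileup on chromosome X, with a CHD8-A minus CHD8-B difference of −0.23, on chromosome 17 (0.14) and on chromosome 8 (−0.0897), and the share of peaks on chromosome 15, with a difference of 0.267 percentage points.

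The lower share of chromosome 19 in CHD8+/− lists was weighed last. A lower copy number shared by both clones is argued against, since the median centred log2 pileup there differed between genotypes by −0.012. By clone, mean centred log2 pileup differed from H66 by 0.013 in CHD8-A and −0.097 in CHD8-B. The latter was the lowest value of CHD8-B on any autosome other than chromosome 20. The pooled value cannot exclude a change in 1 clone. List length stays open. With lists shortened by score to equal length the difference was −0.882 percentage points, 42.7% of the full one, with chromosome 19 at 6.67% of CHD8-A, 5.33% of CHD8-B and 6.88% of H66 peaks. Longer lists may add weaker peaks outside dense chromosomes. At equal length the share of CHD8-A was close to that of H66, and the difference left lay mainly in CHD8-B. Shortening by score within a list makes lengths equal but not enrichment, so what is left in CHD8-B cannot be assigned.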

How the results depend on the processing

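Alternatives with limits of −log10 p, scaling, chromosomes 20 and X left out, both shortest lists left out, and equal-length lists for the chromosome distribution were chosen after seeing the data. Of 209 alternative values, each judged alone, 154 stayed within their bounds, some by construction. H66-only exceeded CHD8-only regions in 2 of 22 alternatives, both with equal list lengths, which favour the class needing fewer calls. The order of CHD8-A and CHD8-B regions turned in 2 of 7, with random thinning (1563.5 against 1711) and without CHD8-B replicate 2 (3867 against 6403). Since 4 against 2 libraries cannot reach 0.05, peak number and covered length were judged against the pooled SD between replicates, 0.21 and 0.27 in log2. Without single libraries they ranged from 0.67 to 1.14 and from 0.68 to 1.23, the extremes without an H66 library. Peak number was 0.64 and 0.68 after scaling by medians and by geometric means at a limit of 4, and 0.14 and 0.22 at a limit of 8. The Jaccard difference ranged from 0.098 to 0.184 without single libraries, where p = 0.0667 without either H66 library because fewer arrangements remain, and was 0.029 (exact permutation p = 0.156) with random thinning, which lowers every overlap by construction.

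Counts of regions also moved. CHD8-only and H66-only regions numbered 279 and 383 with top-scoring lists of equal length, 145 and 798.5 (medians of 20 draws) with random thinning, 1341 and 17 with the higher-scoring 50% of each list, and 4761 and 1289 without H66 replicate 2 and CHD8-B replicate 2. After scaling by medians they were 1564 and 172 at a limit of 4 and 256 and 211 at a limit of 8, and by geometric means 329 and 180 at a limit of 8. At a common limit of 8 without scaling H66-only regions numbered 68. Without single libraries CHD8-only regions ranged from 3237 to 5098 and H66-only regions from 120 to 1199, more by construction since fewer calls or absences are required. Overlap of 50%, joining within 200 bp, autosomes only, the 1 kb distance, and omitting chromosomes 20 and X kept both counts within 1.5 times. Regions of CHD8-A absent from CHD8-B numbered 1069 at equal length and ranged from 3867 to 7665 without single libraries. Those of CHD8-B numbered 900 at equal length and ranged from 2209 to 6403. Chromosomes without overlap between genotypes numbered 10 to 18 without single libraries, with 18 without H66 replicate 1 and 11 without H66 replicate 2 (9.2 by chance in each). They numbered 2 with lists shortened by score, where the chromosome 19 difference was −0.882 percentage points. The excess distance of CHD8-only regions from shared regions was 10.3 kb, and 24.6 kb with a permutation p of 0.0594 at equal length. The causes were not tested. Named windows moved by over 1 SD in 10 of 60 values.

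Replicate differences in pileup correlated between lines at 0.007, −0.017 and −0.041, which cannot exclude pairing in mean pileup. The replicate block takes 9 of the same 15 splits. Its 0.91 and 0.95 in peak number and covered length, smallest exact p = 0.111 and highest count of 2653 CHD8-only regions follow by construction. The comparisons of promoter share, gene list enrichment and peaks near list genes, and their alternatives, were not run. Peaks below the calling limit are unseen, so an absent call is not closed chromatin.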
